A study of Mus musculus with 6 samples.

How the data were processed

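Per the labels' protocols, CD19-positive B cells were enriched from spleens after lysis of red cells, small RNA was isolated with a mirVana kit, and 100 ng of RNA was labelled with Cy3 and hybridised to Agilent mouse miRNA arrays. Per the series' design text, a different mouse was used in each experiment, so the 3 arrays of a group are separate mice. Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.1.1, and the deposited signal intensity of each spot was background-subtracted and spatially detrended but not normalized between arrays. The deposited flags (other values, 0 or 1) state per the file headers whether a spot was well above background, saturated or an outlier. No spot was saturated. The authors also deposited a table of 1 value per miRNA and array, which follows a log2 scale when set against the scanner intensity. Its column medians were -3.26, -3.31, -3.32, -2.88, -3.31 and -3.32 in the order infected 1 to 3 and uninfected 1 to 3. Each median is also the lowest value of its column, held by 76.4% to 85.2% of the miRNAs, so it does not give the centre of the measured levels. How that table was normalized and centred is not given in the sources used here. It holds 1861 of the 1881 miRNAs. Of 257 miRNAs that the scanner software called detected on all 6 arrays, 8 sit at the lowest value of each column in it, among them miR-322-5p.

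Control spots and spots marked as outliers (1306 to 1513 of 56430 per array) were left out, and the background-subtracted intensities of the 7 to 30 spots of a probe were averaged. As 8.65% to 15.1% of the probes were detected per array, each array was divided by its 75th percentile over the 366 probes detected on all 6 arrays, and in the 5-array comparison over the 499 probes detected on all 5 arrays. A probe counted as detected where at least a share of 0.5 of its spots were well above background. Values were then raised to a floor, the median over arrays of the 1st percentile of detected probes (log2 -4.49 with 6 arrays, -3.91 with 5), and log2 was taken. A miRNA's value is the mean over its probes that were detected on all arrays of at least 1 group, which gave 306 miRNAs with 6 arrays and 365 without uninfected array 1. Of the 211 and 267 miRNAs with several such probes, 8 and 13 had probes of opposite sign, and none had probes more than 0.5 apart from 0 in both directions. Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). The 26 miRNA lists, taken from general knowledge of miRNA clusters, seed families and cell types, were tested with camera at a preset correlation of 0.01, where at least 3 members were tested. They were also tested with an estimated correlation and with fry. Figures were drawn with matplotlib 3.10.9.

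The miRNA lists, the tests, most alternatives and the rule for the named miRNAs were fixed before the data were examined. The rule takes up to 12 higher and 12 lower miRNAs of largest change among those past the threshold with no overlap of the groups. Where under 5 pass, it takes the 10 of smallest unadjusted p. It adds the brightest and the changed members of each list, 13 miRNAs of immune, red, endothelial and liver cells, and miRNAs detected in 1 group alone. The same rule was applied to the 5 arrays after the data were seen. A fold against a group in which a miRNA was not detected on every array is a bound: the mean of the brighter group is set against the higher of the miRNA's own signal and the lowest signal of probes well above background on each array.

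No pair of arrays was a duplicate: 36.1% of probes differed by more than 3 standard errors between the closest pair, uninfected arrays 2 and 3. The fits were tested on simulated data, with 60 miRNAs changed in 20 draws from the measured means and residual spreads, taken as independent between miRNAs. With 6 arrays and 306 miRNAs, 45.7% of changes of 2-fold and 84.8% of 4-fold were found, and 4.74% of calls were false. With 5 arrays and 365 miRNAs, the shares were 83.8%, 96.5% and 5.00%. A list lowered by 2-fold was found in all draws. Gene names and neighbours come from a gene table of GRCm38.p6, which names 320 of 365 miRNAs and places 254 within another gene. No coordinate was taken from it.

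Alternatives to the background correction, scaling, value per miRNA, filter, floor, test and blocks were tried, among them the scanner software's total signal per miRNA. The 5-array comparison with all its alternatives, removal of the probes' GC trend and summed probe signals were chosen after seeing the data. For 81 to 102 detected miRNAs per array it exceeded 2 times the summed signal of the miRNA's own detected probes. On infected array 1, for example, it was 541 for miR-342-5p, whose own probes gave 2.95, and 538 for miR-342-3p. No samples were left out of the main comparison.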

Results

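MicroRNA (miRNA) levels were measured in splenic B cells of female C57BL/6 mice, a common inbred laboratory strain, late in infection with *Schistosoma japonicum*, a blood fluke. Spleen cells were taken 13 weeks after infection, at an age of 19 weeks, from 3 infected mice and 3 uninfected mice, and B cells were enriched with magnetic beads against CD19, a surface protein of B cells, to a stated purity of 96%. Each mouse gave 1 array. The arrays were one-colour Agilent mouse miRNA arrays with 4415 probes for 1881 miRNAs, read as fluorescence of Cy3-labelled RNA. Levels are given as log2 values relative to each array's 75th percentile over the 366 probes detected on all 6 arrays, or, in the comparison without uninfected array 1, over the 499 probes detected on the other 5, and changes as infected over uninfected. The number of arrays limits the precision of every value. miRNA names are those of the array files, without the prefix mmu, and genome positions of probes are those of the files, on mouse build mm9.

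The arrays differed in how much miRNA signal they carried, and 1 array stood apart. The 75th percentile of the processed signal was 311, 405 and 394 on infected arrays 1, 2 and 3, 448 and 424 on uninfected arrays 2 and 3, and 120 on uninfected array 1. Across miRNAs, the infected arrays correlated with one another at r = 0.981 to 0.986, and uninfected arrays 2 and 3 at r = 0.994. Uninfected array 1 correlated with the infected arrays at r = 0.925 to 0.928 and with uninfected arrays 2 and 3 at r = 0.837 to 0.839. On it, miR-142a-3p, a bright miRNA of blood cells, had a scaled log2 level of -0.15, against 1.02 to 1.45 on the infected arrays and 2.07 and 2.92 on the other uninfected ones. The difference of the infected mean from uninfected array 2 correlated with that of uninfected array 1 from uninfected array 3 at r = 0.76. These 2 differences share no array, and the 306 miRNAs are not independent replicates. As uninfected arrays 2 and 3 were closely alike, a deviation that they share enters both differences and by itself gives a positive r. The difference of uninfected array 1 from uninfected arrays 2 and 3 rose with the GC content of the probe (Spearman rho = 0.65 across miRNAs), and so did the change in infected cells against uninfected arrays 2 and 3 (rho = 0.50). The comparison is therefore given with all 6 arrays and without uninfected array 1, a choice made after the data were seen. The 5-array values rest on 2 uninfected mice, whose arrays were closer to each other than any infected pair. Over the tested miRNAs, the median SD of the uninfected arrays was 0.54 with 6 arrays and 0.064 with 5. That of the infected arrays was 0.19 and 0.17. The array left out was the one farthest from the other uninfected ones. The SEs and p values of the 5-array comparison can therefore be too small and do not measure the spread between uninfected mice.

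**Figure D1:**
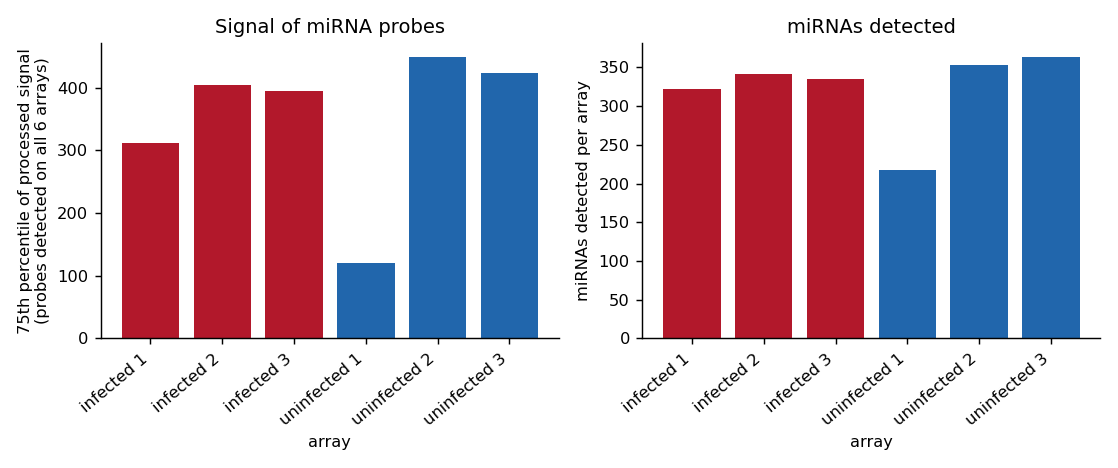
Signal and detection on each array. The left bars give the 75th percentile of the processed signal (arbitrary fluorescence units) over the 366 probes detected on all 6 arrays, and the right bars the number of miRNAs detected, with infected arrays in red and uninfected arrays in blue. Uninfected array 1 had a signal of 120 and 217 detected miRNAs, the lowest of the 6 arrays in both.

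**Figure D2:**
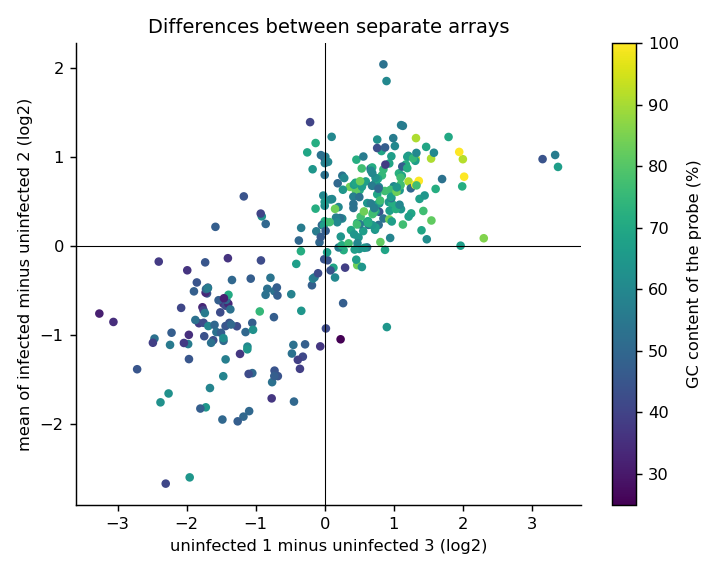
Differences between arrays for 306 miRNAs, as points coloured by the GC content (%) of the miRNA's brightest probe. The horizontal axis is uninfected array 1 minus uninfected array 3 and the vertical axis the mean of the 3 infected arrays minus uninfected array 2, both in log2, and the points follow a rising line with r = 0.76.

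The number of detectable miRNAs per array was compared between the groups. A miRNA was counted as detected when at least a share of 0.5 of the spots of a probe of it were well above background. The infected arrays detected 322, 341 and 335 miRNAs and the uninfected arrays 217, 353 and 363. The means were 333 ± 9.71 (SD, n = 3) and 311 ± 81.6 (SD, n = 3), a difference of 21.7 that was within the spread (exact permutation test, two-sided, p = 1; the smallest p that 3 against 3 can give is 0.1). Without uninfected array 1 the uninfected mean was 358 and the infected mean minus the uninfected mean was -25.3 miRNAs, with every infected array below both uninfected ones, so the direction of this difference depended on that array.

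The comparison of infected with uninfected cells asked which miRNAs of splenic B cells differ in the late phase of infection. With all 6 arrays, 1 of 306 tested miRNAs passed the test: miR-466g, of a family of repeat-rich miRNAs, fell by 1.98 on the log2 scale (SE 0.27, limma adjusted p = 0.0249). It was at least 3.93-fold lower, going from -2.36 ± 0.30 in uninfected to -4.33 ± 0.15 in infected cells (SD, n = 3 each), and was detected on 1 of 3 infected and on 3 of 3 uninfected arrays. Near the threshold lay miR-148a-3p, a miRNA known to act in B cell tolerance and plasma cells, whose probe lies on chromosome 6 from 51219874 to 51219892 on the minus strand. It was detected on 3 of 3 infected and 2 of 3 uninfected arrays. It was at least 1.95-fold higher in infected cells (log2 1.43, SE 0.24, adjusted p = 0.0519), with values of -3.04, -2.82 and -2.94 in infected and -4.49, -4.32 and -4.28 in uninfected cells. The remaining miRNAs among the 10 of smallest unadjusted p did not pass either. Of these, miR-3474, miR-7015-5p, miR-6939-5p, miR-6378, miR-7005-5p and miR-451a had log2 values of 1.69, 1.54, 1.19, 1.13, 0.98 and 0.98, and miR-466i-3p and miR-30a-5p of -1.73 and -1.11 (adjusted p = 0.0790 to 0.107). At an unadjusted p under 0.05, 23 miRNAs were higher and 22 lower. The 3 infected and 3 uninfected values did not overlap for 63 miRNAs, or 20.6% of those tested, where chance gives 10% on average. As the miRNAs are not independent, the share can lie well off 10% by chance. The miR-466g call was lost with normexp background correction, no scaling, the scanner's total or summed probe signals, the authors' value table, no filter on dim miRNAs, a doubled floor, or the replicate or the slide as a block (adjusted p = 0.0507 to 0.926), and a filter on detection on all arrays left it untested. It was also lost without any 1 of the infected arrays, uninfected array 2 or uninfected array 3 (adjusted p = 0.0552 to 0.272), and weights for the arrays by their fit gave 234 miRNAs.

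Without uninfected array 1, 247 of 365 tested miRNAs passed, 121 higher and 126 lower in infected cells, and 82 of them by at least 2-fold (30 higher, 52 lower). All 10 miRNAs of smallest unadjusted p in the 6-array comparison were among them. The comparisons share 5 arrays, and 210 of the 306 miRNAs tested in both passed with 5 arrays, so this is no separate support. miR-181a-5p, which tunes antigen receptor signalling and marks early lymphoid cells, was 5.86-fold lower (log2 -2.55, SE 0.10, adjusted p = 0.000368). miR-322-5p, of the miR-15/16 seed family, whose probe lies on chromosome X from 50407455 to 50407475 on the minus strand, was 6.11-fold lower (log2 -2.61, SE 0.10, adjusted p = 0.000368). Both showed no overlap with uninfected array 1 included, with log2 values of -1.96 (adjusted p = 0.117) and -2.02 (adjusted p = 0.139) over 6 arrays. The other lower miRNAs of largest change were miR-500-3p and miR-6980-5p, at 3.56 and 3.38-fold lower, and, detected on 1 or 2 of the infected arrays, miR-6918-5p, miR-504-3p, miR-7218-5p, miR-6904-5p and miR-466g, at least 6.39, 5.30, 4.76, 4.13 and 3.29-fold lower. miR-129b-5p, miR-1927 and miR-3070-2-3p were not well above background on any infected array and were at least 4.45, 4.30 and 3.45-fold lower. Such bounds set each dimmer array at no less than its lowest signal of probes well above background. Over 6 arrays miR-500-3p and miR-6980-5p had log2 values of -1.15 and -1.04 (adjusted p = 0.395 and 0.418). There miR-6918-5p, miR-504-3p, miR-7218-5p, miR-6904-5p, miR-129b-5p, miR-1927 and miR-3070-2-3p were not tested, since neither group had a probe of them detected on all 3 arrays.

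The higher miRNAs of largest change without uninfected array 1 were led by miR-3474 at 4.15-fold (log2 2.05, SE 0.11, adjusted p = 0.000461) and miR-7015-5p at 3.75-fold (log2 1.91, SE 0.09, adjusted p = 0.000435). miR-711, miR-148a-3p, miR-710, miR-6939-5p, miR-3547-5p, miR-680, miR-6354, miR-125a-3p, miR-6378 and miR-6963-5p followed at 2.71, 2.69, 2.62, 2.45, 2.43, 2.39, 2.38, 2.36, 2.25 and 2.24-fold. Over 6 arrays, those of these 12 that were not among the 10 of smallest p had log2 values of 0.58 to 1.00 (adjusted p = 0.252 to 0.590). With the scanner's total signal over 5 arrays, miR-711, miR-710, miR-3547-5p and miR-6354 changed sign (log2 -0.24, -0.28, -0.32 and -0.035, adjusted p = 0.0673 to 0.944), and miR-125a-3p and miR-6963-5p no longer passed. In the gene table of build GRCm38.p6, miR-3474 lies within Actr5, miR-7015 within Smap2, miR-6939 within Akt1 and miR-711 within Col7a1. Of the 306 miRNAs tested in both comparisons, 210 passed with 5 arrays, and 194 of these had the same sign with 6 arrays. With 6 arrays, 53 of the 210 showed no overlap of the groups, against 63 of all 306. The comparisons share 5 arrays, so agreement in sign is largely built in. With only 1 uninfected array left, assumed to vary like the infected ones, 127 miRNAs passed without uninfected array 2 as well and 108 without uninfected array 3 as well, and 55 of 1881 passed over 5 arrays with no filter on dim miRNAs. Infected array 1 was alone on its slide, which was also scanned apart from the other 5 arrays. Within the other slide, the 2 infected arrays against uninfected arrays 2 and 3 gave 248 of 369 miRNAs, and against all 3 uninfected arrays 0 of 320 (27 at an unadjusted p under 0.05). With the slide as a block, the counts were 234 over 5 arrays and 0 over 6 (26 at an unadjusted p under 0.05). This block fits infected array 1 exactly, so it acts as the omission of that array and is no separate check. Removal of the GC trend of the probes, a choice made after the data were seen, gave 180 miRNAs over 5 arrays and 10 over 6.

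**Figure D3:**
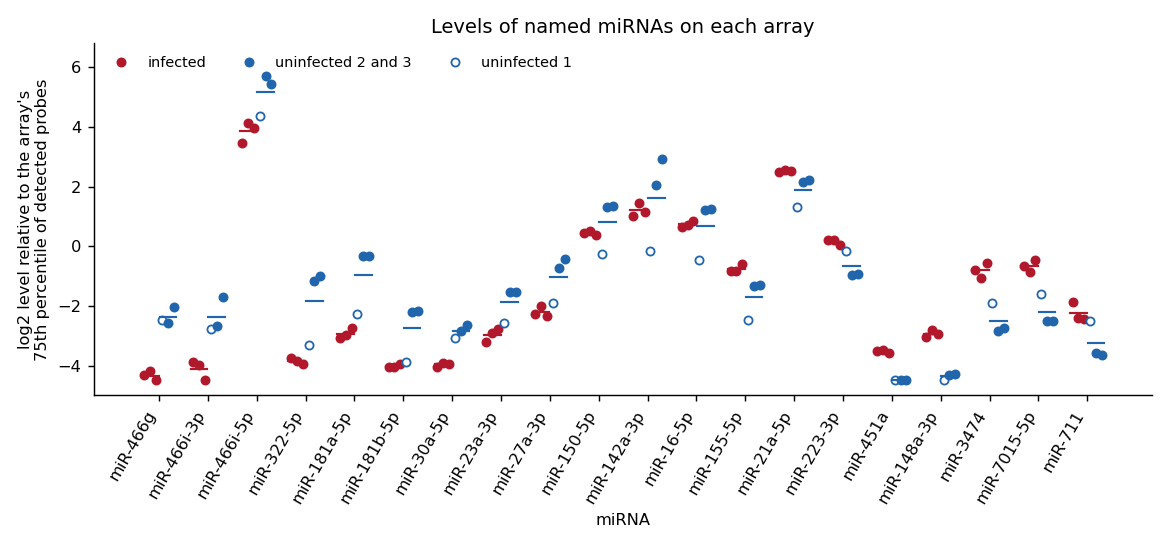
Log2 levels of 20 named miRNAs on each array, relative to the array's 75th percentile of detected probes. Red points are infected arrays, filled blue points uninfected arrays 2 and 3, open blue points uninfected array 1, and lines the mean of each group of 3, with all infected points of miR-181a-5p, miR-322-5p and miR-466g below all uninfected points.

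miRNAs known from B cell activation moved in both directions. miR-155-5p, which B cells need for germinal centre responses, was higher in infected cells by 1.53-fold without uninfected array 1 (log2 0.62, SE 0.10, adjusted p = 0.00592), and its log2 value with 6 arrays was 0.94 (SE 0.36, adjusted p = 0.275). miR-21a-5p, a miRNA raised in many activated cells, was 1.31-fold higher (log2 0.39, SE 0.10, adjusted p = 0.0263; 6 arrays, 0.61, adjusted p = 0.395). For both, every infected value lay above every uninfected value. The 5-array calls were lost without uninfected array 2 or 3 (adjusted p = 0.0532 to 0.135), with no scaling and with scaling over all probes (adjusted p = 0.0632 to 0.721). miR-146a-5p, a brake on NF-kB signalling, had a log2 value of -0.087 with 5 arrays (adjusted p = 0.642), of 0.47 once the probes' GC trend was removed (adjusted p = 0.0236), and of 0.16 with 6 (adjusted p = 0.846). miR-210-3p, which responds to low oxygen, had values of 0.25 (adjusted p = 0.0756) and 0.43 (adjusted p = 0.539). Of the 8 tested miRNAs on the B cell activation list, 3 were higher, 1 was lower and 4 did not pass with 5 arrays, while with 6 arrays none passed over all miRNAs and 1, miR-148a-3p, passed when adjusted over the list alone. The list did not differ from other miRNAs by limma's camera test (adjusted p = 0.0897 with 6 arrays and 0.335 with 5). On the NF-kB responsive list, 2 of 5 were higher, 1 was lower and 2 did not pass with 5 arrays, and none passed with 6 (camera adjusted p = 0.858 and 0.540). With 5 arrays its median of -0.087 and its mean of 0.028 differed in sign. With the GC trend removed, its median was 0.47 and that of the B cell activation list went from 0.28 to 0.53, and neither list passed (adjusted p = 0.0587 and 0.0981).

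The miRNA lists were tested with camera at a preset correlation of 0.01, and none of the calls held with an estimated correlation: each of the 9 lists past the threshold with 5 arrays then had adjusted p = 0.438, and the 4 with 6 arrays adjusted p = 0.704 to 0.844. On the lymphoid-enriched list, with 5 arrays, 10 of 12 tested members were lower, 1, miR-155-5p, was higher and 1 did not pass. Among the lower members, miR-150-5p, known to repress Myb in mature B cells, was 1.77-fold lower (log2 -0.82, SE 0.14, adjusted p = 0.00657), miR-142a-3p, of blood cells in general, 2.32-fold lower (log2 -1.21, SE 0.30, adjusted p = 0.0221) and miR-16-5p 1.34-fold lower (log2 -0.42, SE 0.10, adjusted p = 0.0174). With the GC trend removed miR-16-5p had a log2 value of 0.082 (adjusted p = 0.472) and miR-142a-3p of -0.52 (adjusted p = 0.120), and neither passed. With 6 arrays none of the 3 passed (log2 -0.36, -0.40 and 0.073, adjusted p = 0.722 to 0.935), and uninfected array 1 had lower values of all 3 than the infected arrays. The list passed camera with 5 arrays (median log2 -0.66, adjusted p = 0.00765) and did not with 6 (median -0.26, adjusted p = 0.245). In the same comparison miRNAs of other cells went both ways: miR-223-3p was 2.21-fold higher, and miR-451a and miR-145a-5p were detected on all infected and no uninfected arrays. Lower were miR-139-5p, at 2.94-fold, a further myeloid miRNA and the tested miRNAs of the liver, neural and miR-200 lists. A further 3 lists passed with 5 arrays. The let-7 family had 8 of 9 members lower, among them let-7g-5p at 1.75-fold (GC trend removed, log2 -0.16, adjusted p = 0.175), the miR-15/16 family 5 of 6, and the miR-17-92 and paralog clusters, which promote lymphocyte growth, 9 of 12, among them miR-106b-5p at 2.12-fold (camera adjusted p = 0.0111, 0.0139 and 0.0111). With 6 arrays none of these 3 lists passed (adjusted p = 0.370, 0.370 and 0.615), nor did let-7g-5p (log2 -0.26, adjusted p = 0.831) or miR-106b-5p (-0.37, adjusted p = 0.818). After removal of the probes' GC trend these 4 lists no longer passed with 5 arrays. The median of the lymphoid-enriched list moved from -0.66 to -0.30 (SD over members 0.78 and 1.01, adjusted p = 0.152) and of let-7 from -0.61 to -0.051 (SD 0.39 and 0.31, adjusted p = 0.750). That of miR-15/16 moved from -0.63 to -0.095 (SD 0.90 and 0.84, adjusted p = 0.328) and of miR-17-92 from -0.49 to -0.14 (SD 0.29 and 0.43, adjusted p = 0.281).

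The Sfmbt2 cluster list, the miR-30 family list, the list of the miR-23, miR-27 and miR-24 clusters and the high-numbered list passed camera in both comparisons (with 6 arrays, adjusted p = 0.704 for the first and 0.844 for the others with an estimated correlation). The Sfmbt2 cluster list holds the miR-297, miR-466, miR-467 and miR-669 families, taken by name, and 8 of the 22 measured members lie within the gene Sfmbt2 in the gene table. The gene table places some elsewhere, such as miR-466i-3p and miR-466i-5p within Cdk13 on chromosome 13. It has no match for others, among them miR-466g. Of the 6 members whose probe maps to 1 site in the array files, 5 lie on chromosome 2, the chromosome of Sfmbt2. Among these 5 is miR-669n, which the gene table places within Slc30a7 on chromosome 3. The members of the list have closely similar sequences, and signal shared between them was not measured. With 6 arrays 1 of 16 members was lower over all miRNAs tested and 6 when adjusted over the list alone, and all 16 had values below 0 (median log2 -0.88, camera adjusted p = 7.55e-11). With 5 arrays 12 of 22 were lower (median -1.11, adjusted p = 0.0011), among them the bright miR-466i-5p at 3.15-fold (log2 -1.65, SE 0.29, adjusted p = 0.00796), whereas miR-669l-5p did not pass (log2 -0.99, adjusted p = 0.0926). With 6 arrays these 2 had log2 values of -1.31 and -0.83 (adjusted p = 0.169 and 0.349). The miR-30 family had no member past the test with 6 arrays, 1 of 5 when adjusted over the list alone, and 6 of 6 lower with 5 arrays, among them miR-30a-5p at 2.23-fold and miR-30d-5p at 1.64-fold (medians -0.57 and -0.96, adjusted p = 0.0173 and 0.0111). The miR-23, miR-27 and miR-24 clusters had none with 6 arrays, 2 of 5 when adjusted over the list alone, and 5 of 5 lower with 5 arrays, among them miR-23a-3p at 2.59-fold and miR-27a-3p at 3.02-fold (medians -0.62 and -0.93, adjusted p = 0.0223 and 0.0188). With 6 arrays miR-30d-5p, miR-23a-3p and miR-27a-3p had log2 values of -0.69, -1.09 and -1.19 (adjusted p = 0.179 to 0.245). The high-numbered list, of miRNAs with high numbers in the miRNA catalogue miRBase and so later entries, had no member past the test with 6 arrays (median 0.26, camera adjusted p = 2.45e-06, up), and none when adjusted over the list alone. With 5 arrays 66 of its 127 members were higher, 14 were lower and 47 did not pass (median 0.52, adjusted p = 4.21e-07). With the GC trend removed these 4 lists still passed with 5 arrays, with medians of -0.66, -0.65, -0.71 and 0.25 in the order given (adjusted p = 0.0155, 0.0155, 0.0269 and 0.0269; adjusted p = 0.367 to 0.446 with an estimated correlation).

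The miR-181 family was tested as a list with 5 arrays only, where 4 of 4 members were lower (median -1.27, or -1.24 with miRNAs not well above background at their bound; adjusted p = 0.0111), among them miR-181b-5p at 3.04-fold and miR-181c-5p at least 1.83-fold lower. With the GC trend removed its median was -1.20 (adjusted p = 0.0269; adjusted p = 0.367 with an estimated correlation). With 6 arrays its 2 tested members, miR-181a-5p and miR-181b-5p (log2 -1.27, adjusted p = 0.245), both passed when adjusted over the list alone. limma's fry test, which asks whether the members of a list move one way on balance, gave 0 of 12 lists with 6 arrays and 10 of 14 with 5. With the slide as a block, 3 lists passed over 6 arrays, with medians of -0.70 for the Sfmbt2 cluster, -0.52 for miR-30 and 0.19 for the high-numbered list (miR-23, miR-27 and miR-24 clusters, adjusted p = 0.0558), and 9 lists passed over 5 arrays. On the slide of 5 arrays alone, without infected array 1, the 3 medians were -0.69, -0.48 and 0.20. The slide block also takes out infected array 1 in effect, so these are not separate checks. Without uninfected array 2 or uninfected array 3, the miR-30 list and the list of the miR-23, miR-27 and miR-24 clusters no longer passed with the rest of the 6 arrays (adjusted p = 0.0787 to 0.0893). With uninfected array 1 left out too, the latter list did not pass without uninfected array 2 (adjusted p = 0.0648) or 3 (adjusted p = 0.0542), nor miR-15/16 without uninfected array 3 (adjusted p = 0.0542).

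**Figure D4:**
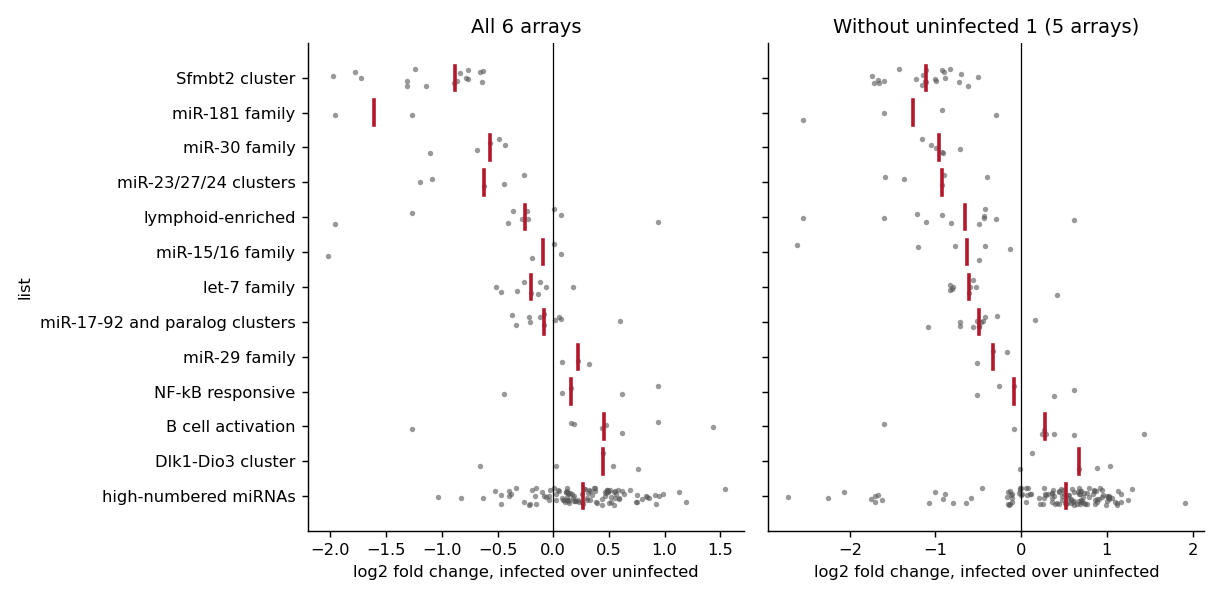
Log2 fold change of each tested member (grey points) of 13 lists, infected over uninfected, with the median of each list as a red line. The left panel uses all 6 arrays and the right panel leaves out uninfected array 1, and in both all tested members of the lists of the Sfmbt2 cluster, miR-181, miR-30, and the miR-23, miR-27 and miR-24 clusters lie below 0.

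The remaining lists of B cell and other miRNAs had few measured members. The miR-29 family had none of 3 past the test with 6 arrays (camera adjusted p = 0.695) and 1 lower with 5 (adjusted p = 0.335). The Dlk1-Dio3 cluster list had 5 of 92 members tested, none past the test with 6 arrays and 2 higher with 5 (adjusted p = 0.540 and 0.331). The tested members did not include miR-3070-2-3p, within Rtl1 on chromosome 12, the chromosome of those tested. That miRNA was lower with 5 arrays, as given above. With 5 arrays the median of miR-29 was -0.33, or 0.32 with the GC trend removed, and with 6 arrays 0.22. In the miR-26 family both tested members were lower with 5 arrays (median -0.93, or -0.33 with the GC trend removed), with miR-26a-5p at 1.92-fold. With 6 arrays neither passed (median -0.38; miR-26a-5p, -0.42, adjusted p = 0.704). In the miR-148 and miR-152 family miR-148a-3p was higher and miR-148b-3p, not tested with 6 arrays, was at least 1.17-fold lower with 5 arrays (GC trend removed, log2 0.27, adjusted p = 0.101). miR-34a-5p, the only detected member of the miR-34 and miR-449 family and a target of p53, was 1.78-fold lower with 5 arrays (adjusted p = 0.00277; 6 arrays, log2 -0.55, adjusted p = 0.536). The list of the miR-99/100 and miR-125 clusters had 1 tested member, miR-10a-5p, which lies within Hoxb3 in the gene table. It was lower with 5 arrays (log2 -0.25, or 0.16 with the GC trend removed) and did not pass with 6 (-0.45, adjusted p = 0.418). The list did not hold miR-125a-3p, which was higher with 5 arrays, as given above, and did not pass with 6 (log2 0.91, adjusted p = 0.339). These values therefore do not show a fall of the clusters. The cluster of miR-183, miR-96 and miR-182 had no detected member.

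miRNAs of other cell types were measured to describe what else the bead-enriched cells could hold. miR-451a, abundant in red cells, which had been lysed, was detected on 3 of 3 infected and on 0 of 3 uninfected arrays and was at least 1.42-fold higher in infected cells over 6 arrays (adjusted p = 0.1) and at least 2.05-fold without uninfected array 1 (adjusted p = 0.00283). Its probe lies on chromosome 11 from 77886689 to 77886709 on the plus strand. It was the only detected member of 7 on the erythroid list. Of 8 miRNAs on the myeloid list, miR-223-3p, abundant in neutrophils, was 2.21-fold higher with 5 arrays (log2 1.15, SE 0.13, adjusted p = 0.00292; 6 arrays, 0.82, adjusted p = 0.245), while miR-139-5p was 2.94-fold lower (adjusted p = 0.000819; 6 arrays, -1.08, adjusted p = 0.328) and 1 further member was lower. The list as a set did not pass by camera (adjusted p = 0.498), while by fry, which does not compare it with other miRNAs, it did (adjusted p = 0.0085). In the authors' value table miR-223-3p had a log2 value of -0.55 with 5 arrays (adjusted p = 0.0525). The endothelial and stromal list had 1 of 14 miRNAs detected, miR-145a-5p, on 3 of 3 infected and 0 of 3 uninfected arrays, at least 1.42-fold higher with 5 arrays (adjusted p = 0.0226, or 0.0857 with the GC trend removed; 6 arrays, adjusted p = 0.418). miR-126a-3p, the main endothelial miRNA, was on no array well above background. The liver miRNA miR-122-5p was not well above background on any array either. The other 2 miRNAs detected on the liver list were lower with 5 arrays (median -0.81), as were both of the epithelial miR-200 family (median -1.03) and 1 neural miRNA (log2 -0.55). With 6 arrays neither liver miRNA was tested, and the 1 tested miRNA of the miR-200 family and the neural miRNA did not pass (log2 -0.53 and -0.15, adjusted p = 0.615 and 0.866). None of 6 muscle miRNAs was detected, and the 1 detected miRNA of the T cell list was miR-146a-5p. Over all miRNAs, 17 were detected on all 3 infected arrays and no uninfected array and 2 the reverse. Without uninfected array 1, 17 were detected on all infected and neither uninfected array and 35 the reverse. These counts need detection on different numbers of arrays, and uninfected arrays 2 and 3 had the highest signal before scaling.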

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

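All alternatives for the 5 arrays, the joint omissions of arrays, the removed GC trend and summed probe signals were chosen after seeing the data. The miRNA count with 6 arrays, 1 as reported, was 0 with normexp background (42 at an unadjusted p under 0.05), no scaling (63), detection on all arrays (28), a replicate block (60) and a slide block (26), and 2 with the brightest probe and with eBayes trend and robust. It was 4 with the 75th percentile over all probes and with no filter on dim miRNAs, 5 in the authors' value table, 6 with the floor doubled, 10 with the GC trend removed, 12 with quantile normalization, 20 with summed probes, 23 at an unadjusted p and 2-fold, and 24 with the scanner's total signal. It was 234 with array weights, 218 without uninfected 1 over the same miRNAs, 248 without uninfected 1 and infected 1, and 0 to 247 with 1 array left out, where 247 came without uninfected 1 and 0 without any other (24 to 42 at an unadjusted p under 0.05). The cause was not tested in these cases. The count of lists with 6 arrays, 4 as reported, was 9 with no filter, 8 with array weights, 8 without uninfected 1 over the same miRNAs, 9 without uninfected 1 and infected 1, 0 with an estimated correlation and 0 with fry, 3 to 9 with 1 array left out, and 3 to 6 otherwise. With 5 arrays the count of 247 miRNAs was 55 with no filter, where 1881 were tested, 82 at an adjusted p and 2-fold, 84 at an unadjusted p and 2-fold, 108 to 249 with 1 more array left out, and 174 to 260 otherwise. The labels do not state whether the replicate numbers pair the samples, and a block on them gave 228. With uninfected 1 left out, infected 1 has no partner, so this block also takes out infected 1 in effect. The count of 9 lists was 5 with the GC trend removed, where the medians of the 4 that ended moved toward 0, the spread of members rose in miR-17-92 and lymphoid-enriched, and the cause was not tested. It was 0 with an estimated correlation, 7 to 9 with 1 more array left out, and 8 to 10 otherwise. The difference in detected miRNAs of 21.7 was 38.7 by the scanner's call, 18.3 with every spot well above background, and -25.3 to 47.7 with 1 array left out.

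Scaling moved the median change of all miRNAs with 6 arrays by 0.21 (75th percentile over all probes), 0.11 (quantile), -0.14 (median of detected probes) and 0.37 (none), and with 5 arrays by -0.31 (none), and single values under these settings are given relative to those shifts. Of the named miRNAs, these changed sign with 6 arrays, all in log2. With normexp background miR-146a-5p had -0.065, miR-16-5p -0.0061 and miR-210-3p -0.10, and with no scaling miR-210-3p had -0.14 and miR-145a-5p -0.044. With the scanner's total signal miR-6378 had -0.28, miR-711 -0.012, miR-710 -0.044, miR-3547-5p -0.33 and miR-6354 -1.84. With array weights miR-146a-5p had -0.093 and miR-16-5p -0.44, and in the authors' value table miR-223-3p -0.38 and miR-181b-5p 0.66. With the GC trend removed let-7g-5p had 0.048. Without uninfected 1 miR-146a-5p had -0.087 and miR-16-5p -0.42, over the same miRNAs also -0.087 and -0.42, and without infected 1 too miR-16-5p had -0.37. With 1 array left out the ranges were -0.087 to 0.32 for miR-146a-5p, -0.42 to 0.36 for miR-16-5p, -0.80 to 0.039 for let-7g-5p, -1.21 to 0.25 for miR-142a-3p and -1.09 to 0.079 for miR-106b-5p. With 5 arrays the scanner's total signal gave -0.053 for miR-210-3p, -0.24 for miR-711, -0.28 for miR-710, -0.32 for miR-3547-5p, -0.035 for miR-6354 and 0.30 for miR-148b-3p. The authors' value table gave -0.55 for miR-223-3p and 0.020 for miR-322-5p, which sits at that table's lowest value. The GC trend removed gave 0.47 for miR-146a-5p, which then passed (adjusted p = 0.0236), 0.082 for miR-16-5p, -0.0077 for miR-210-3p and 0.27 for miR-148b-3p. A replicate or slide block, either of which takes out infected 1 in effect, gave 0.044 for miR-146a-5p. Its range with 1 more array left out was -0.16 to 0.023. The cause of these changes was not tested. Of the values of named miRNAs under alternatives that left out no array, 751 with 5 arrays kept direction and side of the threshold, 69 no longer passed and 3 newly passed, and with 6 arrays these counts were 576, 9 and 86. No list past the threshold changed its camera direction. Signal over background limits the dim miRNAs: the 75th percentile was 39.7 to 139 times the spread (SD) of the negative controls. The lowest ratio, 39.7, was that of uninfected 2, whose negative controls had an SD of 11.3, against 2.86 to 4.19 on the other arrays. Uninfected 1 had a ratio of 42.0 and detected 217 miRNAs.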

Other observations

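The tests on uninfected array 1, on a shared change of that array and the infected arrays by correlation, and on repeats outside the Sfmbt2 list were chosen after the results were seen. miRNAs encoded close together differed less in their change than random pairs did. With 5 arrays, 22 pairs of neighbouring miRNAs within 10 kb, formed from 40 miRNAs, differed in log2 change by 0.564 on average, against 0.826 in random pairs (one-sided permutation test with 100000 resamples, p = 0.00802), so random pairing did not account for it. miR-23a-3p and miR-27a-3p, with probes on chromosome 8 from 86732466 to 86732482 and from 86732631 to 86732646, were a similar pair, at log2 -1.37 and -1.59, whereas 5 of the 22 pairs had opposite signs, such as miR-652-5p and miR-652-3p at 0.30 and -1.42, named after their values were seen. The pairs included 2 arms of 1 precursor and relatives of similar sequence, and the GC content of probes was not accounted for, so joint transcription is 1 of several open explanations.

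Without uninfected array 1, 35 miRNAs were detected on both uninfected arrays and no infected array, and 17 on all 3 infected arrays and neither uninfected array. The counts are not alike, since the first needs detection on 2 arrays and the second on 3. Detection was also called before scaling, and uninfected arrays 2 and 3 had the highest 75th percentiles of signal (448 and 424, against 311 to 405 on the infected arrays). Among the former were miR-129b-5p, miR-1927, miR-3070-2-3p and miR-181c-5p, and among the latter miR-451a and miR-145a-5p.

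Uninfected array 1 had 0.276 times the miRNA signal of uninfected arrays 2 and 3. A failure of labelling or hybridisation that lowered all signals was argued against by the spike-in controls, whose ratio was 0.910 as a geometric mean of 4, and a swap between the groups by the infected arrays, each of which correlated better with the other infected arrays than with uninfected arrays 2 and 3 (smallest margin 0.0451). A single wrong label or a different cell mixture in this mouse was not tested. RNA amount or quality that acts on probes by GC content remains a candidate explanation, since the difference of this array followed probe GC (rho = 0.645), and the signals of 5 further control probes were 0.335 to 0.599 of those on uninfected arrays 2 and 3.

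With 5 arrays 66 of 127 high-numbered miRNAs were higher in infected cells and 14 lower, and with 6 arrays none passed (the list, adjusted p = 0.438 and 0.844 with an estimated correlation), and their probes had a median GC content of 64.3%, against 52.9% for other miRNAs. With each array's GC trend removed, the list's median difference from other miRNAs fell from 0.86 to 0.36 in log2 with 5 arrays, or to 41.6% of its size, between the bounds set for and against GC content as the cause, so its share stays undecided. The list still passed camera (adjusted p = 0.0269; adjusted p = 0.446 with an estimated correlation). The test of a shared change took all 306 miRNAs, not the list alone. It set the infected mean minus uninfected array 2 against uninfected array 1 minus uninfected array 3. The r was 0.759, and 0.755 with uninfected arrays 2 and 3 exchanged, as the explanation of a shared technical or RNA-related shift would need. Uninfected arrays 2 and 3 correlated at r = 0.994, so a deviation that they share enters both differences and also gives a positive r. These values therefore cannot show whether the list changed on uninfected array 1. The GC trend was fitted on all miRNAs, the list included, so a true change of the list would be partly removed with it. Infection stays open as a cause for the removed part and for the part kept, and was not tested apart from GC content.

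Of the Sfmbt2 list 1 of 16 members was lower in infected cells with 6 arrays and 12 of 22 with 5 (the list, adjusted p = 0.704 and 0.438 with an estimated correlation), and its probes share dinucleotide repeats. The 4 tested miRNAs outside the list with at least 2 such repeats in a probe, miR-1187, miR-3082-5p, miR-32-3p and miR-574-5p, named after their values were seen, had log2 changes of -1.12, -1.22, -0.69 and -1.28 with 6 arrays, a median of -1.17. Probe sequence may therefore account for the pattern in place of, or beside, lower transcription of the cluster, and lower transcription in infected cells was not tested separately.

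Splits of the 6 arrays into other groups of 3 were too few, at 10, for a share under 0.05. The real split gave 1 miRNA and the highest of the others 0, so 1 of 10 splits gave as many. For the lists the real split gave 4 and the highest of the others 9, and 9 of 10 splits gave at least as many. Infected arrays 1 and 3 with uninfected array 1 against the rest gave 9 lists and 122 miRNAs at an unadjusted p under 0.05, against 45 for the real split. That split sets infected array 2 with uninfected arrays 2 and 3. Infected array 2 correlated with these at r = 0.935 and 0.932, and with uninfected array 1 at 0.927. Uninfected array 1 correlated with the infected arrays at 0.925 to 0.928, below the 0.981 to 0.986 among them. The low miRNA signal of this array can lower its r with any array. These values therefore cannot tell whether its sample was like the infected ones.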
